A study of Solanum lycopersicum with 12 samples.

How the data were processed

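Root RNA of salt-treated tomato seedlings was compared with RNA of control seedlings on 2-colour arrays of clones from subtracted libraries. The 12 arrays cover 2 genotypes, ZS-5 and LA2711, at 3 times of treatment (30 min, 2 hr and 6 hr), with 2 arrays for each of the 6 conditions. Per the labels, the dyes were swapped between the 2 arrays of a condition. A dye-swap pair was therefore counted as 1 replicate and averaged to 1 value, so that every fit uses 6 values. Nothing in the labels says whether the plants of different times were grown and harvested separately, or whether one control plant served several times, so p-values measure only the spread between these conditions, which may be partly technical.

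The deposited values are 1 log2 ratio per spot and array. The scanner, the background correction and the normalization are not given in the sources used here. The underlying ratios were taken to have limits at 0.001 and 100000. Counted as at the limits were the 366 spot values whose ratio, or its inverse, was 0.001 or less. On the arrays with treated RNA in Cy5, the inverse of the ratio was a number of 3 decimals for 100.0% of the spots, while the ratio itself was one for 18.4% to 25.6%. On the arrays with treated RNA in Cy3, the ratio itself was one for 100.0% of the spots and its inverse for 18.8% to 49.3%. The authors thus turned the sign of one dye orientation before depositing the log2 ratios, and all 12 arrays run the same way. Which condition is the numerator stays unknown, because the dye order of the underlying ratio is not given in the sources used here. The text speaks for this reason of a positive side and a negative side, which stand for higher in one of the treated and control RNAs and lower in the other. Intensities were not used here, so that neither signal over background nor the depth behind a ratio is known, and the number of arrays limits the precision.

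The array has 10368 spots, of which 9013 to 9900 held a value on each array. Spots came in adjacent sets of 3 with nearly the same ratios: the SD within a set was 0.096 to 0.16, against 0.36 to 0.963 for sets shifted by 1 spot. Each set was taken as 1 clone and its measured spots were averaged, which gave 3456 clones. Spots at the ratio limits were left out, a choice made after seeing the data. The 3018 clones measured on all 12 arrays were tested and the other 438 were not. A platform annotation names 237 spots, which are 79 clones of 38 genes, with 0 spots of several genes. The remaining 3377 clones are unnamed here. Of the 38 genes, 37 were found by gene ID in the RefSeq gene table of assembly SLM_r2.1, which changed 0 symbols. The 77 named clones measured on all arrays stand for 36 genes. Clones are identified by gene and by the numbers of their spots, and no genome coordinates are given because the files name no build.

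Each array was centred on its median over the 3018 clones, as fixed before the data were examined. Before centring, the means of the array medians were -0.02, 0.01 and -0.85 in ZS-5 at 30 min, 2 hr and 6 hr, and 0.22, -0.35 and -0.98 in LA2711. Centring therefore adds 0.85 to 0.98 to each 6 hr value, and uncentred values are printed beside centred ones where this matters. Tests were made with limma 3.58.1 (lmFit and eBayes, 2-sided, in R 4.3.3) with Benjamini-Hochberg adjustment at 0.05. The mean log2 ratio was tested against 0 over all 6 conditions, within each genotype (spread shared between genotypes, 4 residual degrees of freedom) and at each time (spread shared between times, 3 residual degrees of freedom). A value at a single time is the mean of both genotypes, so a difference between them counts as spread. The LA2711 minus ZS-5 difference was tested with time as a covariate, and the 6 hr minus 30 min difference with genotype as a covariate. A single condition has 1 replicate and no test: clones at least 2-fold from 0 on both arrays were counted, beside clones past 2-fold with opposite signs. Called means an adjusted p under 0.05.

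The script was tested on simulated data over 3018 clones with 200 changed clones. It recovered 16% of changes of log2 1 and 84% of log2 2 over all 6 conditions. In ZS-5 it recovered 0% and 0%, and in LA2711 0% and 9%. For the difference between genotypes it recovered 73% and 100%, at 30 min 70% and 100%, at 2 hr 73% and 100%, at 6 hr 74% and 99%, and for 6 hr minus 30 min 39% and 99%.

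Fixed before the data were examined were 20 gene lists, defined by patterns in gene symbols or descriptions. Only symbols and synonyms were matched here, so the heat shock protein gene MTSHP and the glucanase gene GluB are in no list. Matched in this way, 8 lists hold 0 named clones and 3 hold the minimum of 5 measured clones. These 3 were tested with camera at its preset correlation of 0.01, with an estimated correlation, and with fry. The named genes were chosen by a rule also fixed then. For each tested comparison it takes the called named clones with the 10 largest values on each side, 1 clone per gene, the one with the smallest p. Where under 5 passed, it takes the 5 with the smallest p. It adds the 5 largest on each side for each condition among clones past 2-fold on both arrays, up to 4 members of each list with the smallest p over all 6 conditions, and a set of salt-response genes of which NP24 and an S-adenosylmethionine synthetase gene have a named clone. Other settings fixed before the data were examined were 12 separate arrays, a replicate block, a dye term, no centring, quantile normalisation, a looser filter on missing values, no covariate, other thresholds, and leaving out arrays or conditions. Added after seeing the data were keeping spots at the limits, scaling each array to the same median absolute deviation in the tested comparisons, and testing against a 2-fold change with treat. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.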

Results

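The series measured root transcripts of tomato seedlings under salt stress in a salt-sensitive genotype, ZS-5, and a salt-tolerant genotype, LA2711. Treated and control RNA of each genotype were hybridised together after 30 min, 2 hr and 6 hr, on 2 arrays per condition with the dyes swapped. The 12 arrays gave log2 ratios of 3018 clones measured throughout, of which 77 carry the names of 36 genes. Values are log2 ratios of the 2 RNAs, all run the same way, but which RNA is the numerator is not settled. Positive and negative values are therefore opposite sides of the salt response, and neither is called an induction. Each array was centred on its median unless a value is said to be uncentred.

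The first question was which genes responded to salt at each time. At 30 min the largest named response was that of LOC778326, with all 12 of its clones called on the positive side and a median of 3.20. One clone of AOS, which encodes allene oxide synthase of jasmonate synthesis (spots 1540 to 1542), lay at 2.79 ± 0.23 (SE, mean of both genotypes, spread from 6 conditions, limma adjusted p = 3.49e-05). Of the 7 AOS clones, 4 were called positive and 2 negative, the lowest at -1.75. LOC778302 lay at 1.87, DES, a divinyl ether synthase, at 1.68, GS2 at 1.56, one clone of NAC1, a NAC-domain transcription factor, at 1.53, LOC544267 at 1.52, and JERF1, an ethylene response factor, at 1.17. The beta-1,3-glucanase gene GluB lay at 1.12 and the potassium channel gene LKT1 at 1.02. On the negative side were AADC1B, an aromatic amino acid decarboxylase, at -1.47, the metallothionein gene MT2 (spots 8869 to 8871) and the catalase gene cat1, both at -1.43, LOC543942 at -1.16, and the ethylene response factor gene ERF3 at -1.14. PSBR, of photosystem II, lay at -0.90 in the 1 of its 3 clones that was called, ribA at -0.89 and the amino acid permease gene AAP2 at -0.88. With limma, 550 of 3018 clones were called at 30 min, 286 positive and 264 negative. Without both ZS-5 arrays of 30 min the count was 238, and after quantile normalisation it was 1665.

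At 2 hr the negative side held the largest values. LOC543942 lay at -4.76 ± 0.24 (SE, mean of both genotypes, spread from 6 conditions, limma adjusted p = 8.69e-07), AOS (spots 1384 to 1386) at -4.74, PSBR (spots 1453 to 1455) at -4.28, AADC1B at -3.60, NAC1 (spots 3064 to 3066) at -3.56 and ribA at -3.55. MT2 (spots 8869 to 8871), whose 3 clones do not agree in sign, followed at -2.40, ERF3 at -1.93, AAP2 at -1.85 and the beta-amylase gene BMY3 at -1.82. AOS and NAC1 each also had 1 clone called positive, at 3.17 and 1.14. The other PSBR clones lay at -0.95 and -0.85. On the positive side LOC778326 (spots 5401 to 5403) lay at 3.88, the alcohol dehydrogenase gene ADH2 at 3.51 ± 0.79, GluB (spots 4516 to 4518) at 3.27, LOC543878 at 3.05, GS2 at 2.81 and LOC544267 at 2.76. Smaller positive values were those of DES at 1.77, LKT1 at 1.75, the peroxidase gene TPX2 at 1.46, whose call was lost without centring (adjusted p = 0.0543), and JERF1 at 1.21. In all, 2078 clones were called, 972 positive and 1106 negative, or 46.8% positive. Without centring 36% of the calls were positive.

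At 6 hr the genes named on the negative side at 2 hr lay further from 0. Those on the positive side were mixed in centred values. GS2 rose from 2.81 to 3.56, LKT1 from 1.75 to 2.60 and TPX2 from 1.46 to 2.21, and LOC778326 and LOC543878 rose too. ADH2 fell from 3.51 to 3.31, JERF1 from 1.21 to 0.83 and DES from 1.77 to -0.54 (not called). The GluB and LOC544267 clones named there also fell. Uncentred 2 hr and 6 hr values were 2.64 and 2.65 for GS2 and 1.58 and 1.68 for LKT1. They were 1.29 at both times for TPX2, and 3.33 and 2.39 for ADH2. LOC543942 lay at -5.71 ± 0.24 (SE, mean of both genotypes, spread from 6 conditions, limma adjusted p = 2.26e-07), NAC1 (spots 3064 to 3066) at -5.47, AOS (spots 1384 to 1386) at -5.24 and PSBR (spots 1453 to 1455) at -5.17. AADC1B lay at -4.50, ribA at -4.26, BMY3 at -3.59, MT2 (spots 8869 to 8871) at -3.03, the mitochondrial small heat shock protein gene MTSHP at -3.03 and the phytoene synthase gene PSY2 at -2.93. On the positive side LOC778326 (spots 9292 to 9294) lay at 4.90, LOC543878 (spots 9973 to 9975) at 3.83, GS2 at 3.56, ADH2 at 3.31 and the S-adenosylmethionine synthetase gene SAM3 (spots 8152 to 8154) at 3.08. GluB lay at 2.97, LKT1 at 2.60, the tonoplast aquaporin gene TIP at 2.59, the glutamate decarboxylase gene GAD2 at 2.43 and TPX2 at 2.21. Uncentred, these positive values were smaller by 0.91 or 0.92, for example 3.99 for LOC778326 and 2.65 for GS2, and the negative ones larger, for example -6.63 for LOC543942. All 20 of these clones kept their side and their call without centring. Other clones of the same genes lay elsewhere, in centred values. PSBR clones lay at -1.45 and -1.27, and the highest clones of AOS, NAC1 and MT2 at 3.49, 1.41 and 2.09. The positive calls of NAC1 and MT2 were lost without centring. The lowest clones of LOC543878, SAM3 and LOC778326 lay at 0.75, 0.32 and 1.65. The ADH2 mean joins unlike genotypes, 5.45 in ZS-5 and 1.16 in LA2711. The 105 clones within 0.25 of 0 at 30 min and 2 hr in both genotypes had uncentred 6 hr medians of 0.07 in ZS-5 and -0.10 in LA2711, so centring placed them on the positive side. In all, 2635 clones were called, 1356 positive and 1279 negative, or 51.5% positive. Without centring 2472 were called, of which 35.7% were positive.

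Within a condition there is 1 replicate and no test, so the counts describe these arrays. The clones come from subtracted libraries and several can share a gene, so the shares are of clones, not of root genes. Past 2-fold on both arrays, ZS-5 had 501 of 3018 clones at 30 min (16.6%), 1434 at 2 hr (47.5%) and 2225 at 6 hr (73.7%). LA2711 had 297 (9.8%), 1240 (41.1%) and 2033 (67.4%). With each array scaled to the same median absolute deviation, the counts were 1223, 1249 and 1276 in ZS-5 and 929, 1247 and 1267 in LA2711. This scaling forces all arrays to the same spread, so it cannot decide whether the rise with time is real. Clones past 2-fold with opposite signs on the 2 arrays numbered 1 or 2 in each condition. In ZS-5 the positive and negative counts were 323 and 178, 585 and 849, and 1100 and 1125. In LA2711 they were 161 and 136, 425 and 815, and 972 and 1061. Centring moved this split: 49.4% of the ZS-5 clones at 6 hr were positive with it and 33.7% without, and in LA2711 the shares were 54.2% and 66.1% at 30 min, 34.3% and 19.8% at 2 hr, and 47.8% and 26.4% at 6 hr. A clone of GAD2 lay at 3.0 ± 0.17 (SD, n = 2 arrays) in ZS-5 at 30 min and LOC543916 at 2.98 ± 0.11. ADH2 lay at 5.45 ± 0.01 in ZS-5 at 6 hr and at 1.16 ± 0.46 in LA2711, or at 4.60 and 0.18 uncentred.

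**Figure D1:**
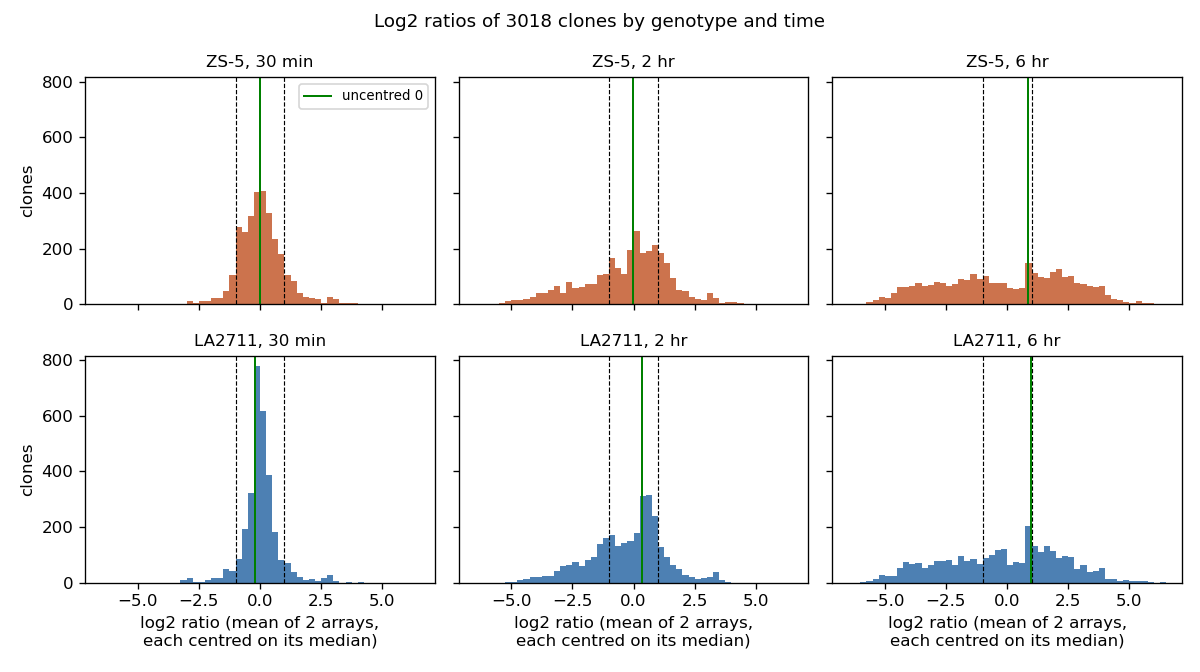
Histograms of the log2 ratio of 3018 clones (x axis, mean of 2 arrays, each centred on its median) for each genotype and time, with the number of clones on the y axis. Dashed lines mark 2-fold and the green line marks where an uncentred ratio of 1 falls; the SD over clones was 0.94, 1.78 and 2.59 in ZS-5 and 0.75, 1.55 and 2.42 in LA2711 at 30 min, 2 hr and 6 hr.

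The next question was how the response differed between 6 hr and 30 min. The largest differences were on the negative side, where NAC1 (spots 3064 to 3066) differed by -6.80 ± 0.34 (SE, mean of both genotypes, spread from 6 conditions, limma adjusted p = 2.49e-05) and AOS (spots 1384 to 1386) by -6.53 ± 0.32. Both clones had positive values at 30 min in both genotypes and negative ones at 2 and 6 hr. LOC543942 differed by -4.56, PSBR (spots 1453 to 1455) by -4.27, ribA by -3.37, MTSHP by -3.11, BMY3 by -3.09, AADC1B by -3.03, the phosphoenolpyruvate carboxylase kinase gene PPCK1 by -2.48 and DES by -2.22. Positive differences were those of LOC543878 (spots 9973 to 9975) at 3.17, TIP at 3.01, cat1 at 2.90, ADH2 at 2.83, SAM3 (spots 4396 to 4398) at 2.24, GS2 at 2.00, GluB at 1.93, gts1 at 1.59, LKT1 at 1.57 and LOC778326 (spots 5401 to 5403) at 1.52. Lost without centring were the positive calls of ADH2 (adjusted p = 0.129), GS2 (0.1), GluB (0.0583), gts1 (0.283), LKT1 (0.202) and LOC778326 (0.193). Other clones of these genes differed, in centred values. PSBR ranged up to -0.58 with 1 of 3 clones called, NAC1 up to 2.03 and AOS up to 0.70. LOC543878 ranged down to -0.22 (2 of 3 called), SAM3 to -0.41 (3 of 5) and LOC778326 to -0.20 (8 of 12). The rule of 1 clone per gene left out an MT2 clone called positive at 2.78. In all, 2337 clones were called, 1255 positive and 1082 negative, or 53.7% positive, against 1842 and 26.7% without centring. After quantile normalisation 1114 were called, and AADC1B lay at 0.01, GS2 at -0.19, LKT1 at -0.41 and LOC778326 at -0.61, on the other side of 0. With each array scaled to the same median absolute deviation, an alternative added after seeing the data that forces all arrays to the same spread, 808 were called. There SAM3 at -0.35, GS2 at -1.95, GluB at -0.74, LKT1 at -1.14, LOC778326 at -5.20, ribA at 0.02 and AADC1B at 1.35 changed sign.

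**Figure D2:**
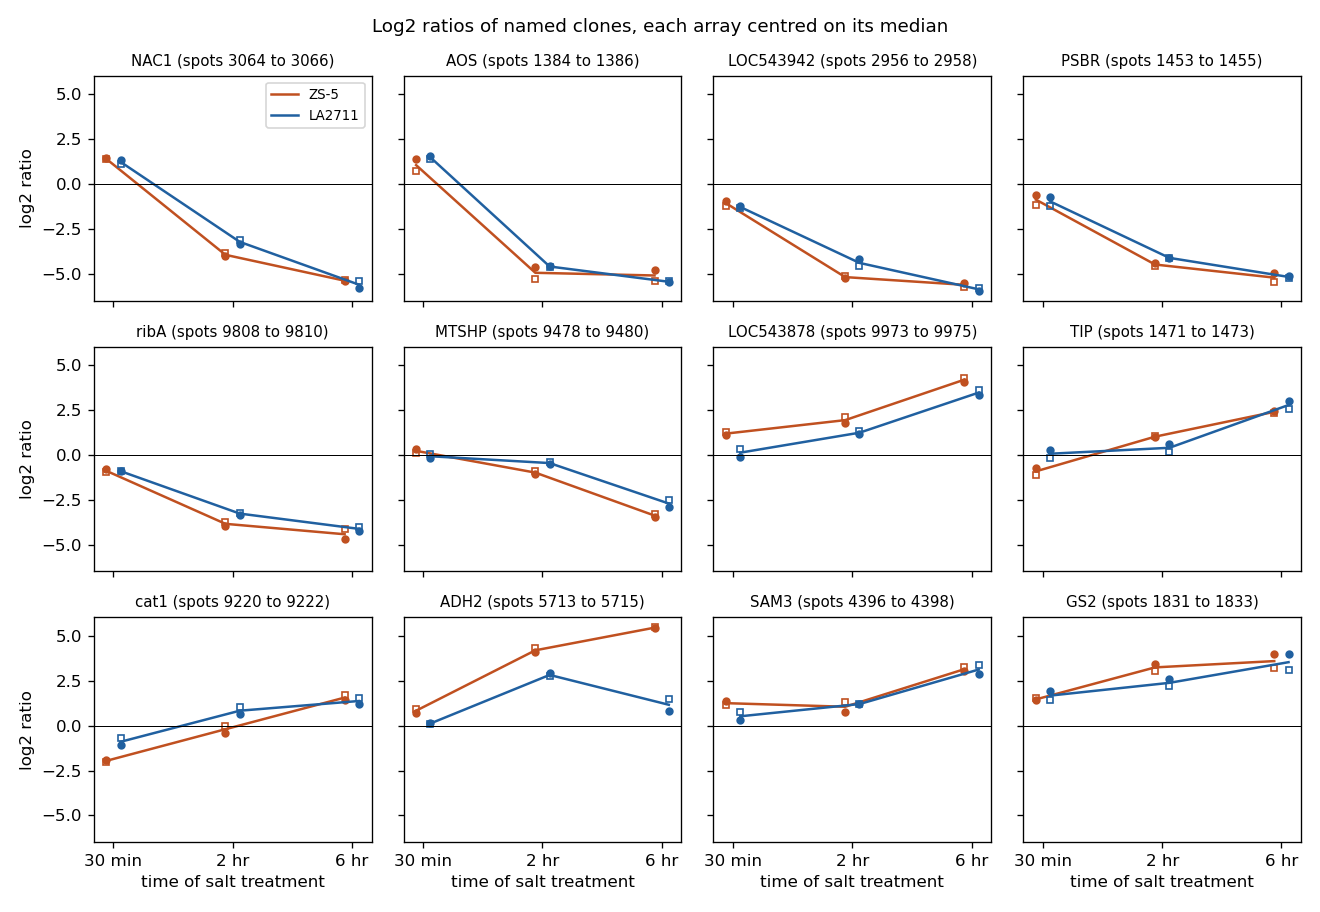
Log2 ratios (y axis, centred) at 30 min, 2 hr and 6 hr of salt treatment (x axis, evenly spaced) for the 6 named clones with the largest negative and the 6 with the largest positive difference between 6 hr and 30 min. Circles and squares are the 2 arrays of a condition and lines join their means; the means of NAC1 and AOS lie above 0 at 30 min and below -5 at 6 hr in both genotypes, and ADH2 parts the genotypes at 6 hr.

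Over both genotypes and all times, LOC778326 (spots 5065 to 5067) lay at 3.37 ± 0.20 (SE, n = 6 conditions, limma adjusted p = 8.92e-05) and AOS (spots 1540 to 1542) at 3.15 ± 0.22. LOC543878 lay at 2.72, GS2 at 2.65, ADH2 at 2.43, GluB at 2.07, LOC544267 at 2.05, LKT1 at 1.79, SAM3 at 1.59 and TPX2 at 1.56. On the negative side were LOC543942 at -3.88, PSBR (spots 1453 to 1455) at -3.45, AADC1B at -3.19, ribA at -2.90, NAC1 (spots 1408 to 1410) at -2.29, MT2 (spots 8869 to 8871) at -2.28, BMY3 at -1.97, ERF3 at -1.92, PSY2 at -1.90 and AAP2 at -1.74. The call of NAC1 was lost without centring (adjusted p = 0.0646). No other of the 9 NAC1 clones was called. At 30 min the called clone lay at 0.89 in ZS-5 and 0.73 in LA2711, so its mean joins both sides. The other MT2 clones lay at -0.62 and 0.74 and were not called. Of the 7 AOS clones, 1 was called positive and 5 negative. In all, 1782 clones were called, 833 positive and 949 negative. The count was 605 without both arrays of ZS-5 at 2 hr, 847 without those of ZS-5 at 6 hr, 716 without those of LA2711 at 2 hr and 645 without those of LA2711 at 6 hr, and 167 when tested against a 2-fold change with treat, an alternative added after seeing the data.

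Within ZS-5 alone, LOC778326 lay at 3.49 ± 0.34 (SE, limma adjusted p = 0.00536), LOC543878 at 3.35, AOS (spots 1540 to 1542) at 3.27, GluB at 3.22, GS2 at 2.76 and MT2 at -2.39. The GluB and MT2 calls were lost without centring (adjusted p = 0.0661 and 0.0787). Within LA2711, LOC778326 lay at 3.26 ± 0.34 (limma adjusted p = 0.00653), AOS (spots 1540 to 1542) at 3.03 and LOC544267 at 2.17, the last with an adjusted p of 0.14 without centring. In each genotype 1 of the 7 AOS clones was called positive and 1 negative. The median of the AOS clones was -2.56 in ZS-5 and -2.54 in LA2711. MT2 at -2.17 (adjusted p = 0.0556) and GS2 at 2.53 (adjusted p = 0.0568, and 0.0446 without centring) did not pass in LA2711 with centring. Called were 168 clones in ZS-5, 89 positive and 79 negative, and 128 in LA2711, 72 positive and 56 negative. Without centring 78.5% of the ZS-5 calls were positive, against 53% with it. These tests take the change over time within a genotype as spread, and both counts were 0 without the 2 hr arrays of the genotype tested. The ZS-5 count was 975 without the ZS-5 arrays of 30 min, 59 without those of 6 hr and 979 after quantile normalisation. The LA2711 count was 62 without the LA2711 arrays of 30 min, 0 without those of 6 hr and 936 after quantile normalisation.

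The comparison of LA2711 with ZS-5 asks which responses differ between the tolerant and the sensitive genotype. No clone was called by limma (0 of 3018, with 196 at an unadjusted p under 0.05), and the 5 named genes with the smallest p did not pass. LOC543916 differed by -1.72 ± 0.33 (SE, n = 6 conditions, limma adjusted p = 0.471), LOC544267 (spots 5749 to 5751) by -1.55, GluB by -1.21, LOC543878 by -0.83 and PSY2 by 0.88. ADH2 differed by -2.12 and was not called either. A genotype difference that varies with time counts partly as spread in this test. The count of 0 therefore does not exclude differences at single times. With the 12 arrays taken as separate samples, 219 clones were called, but this counts each dye-swap pair as 2 samples. Across clones, which are not independent replicates, the log2 ratios of both genotypes correlated with r = 0.81 at 30 min, 0.94 at 2 hr and 0.98 at 6 hr.

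**Figure D3:**
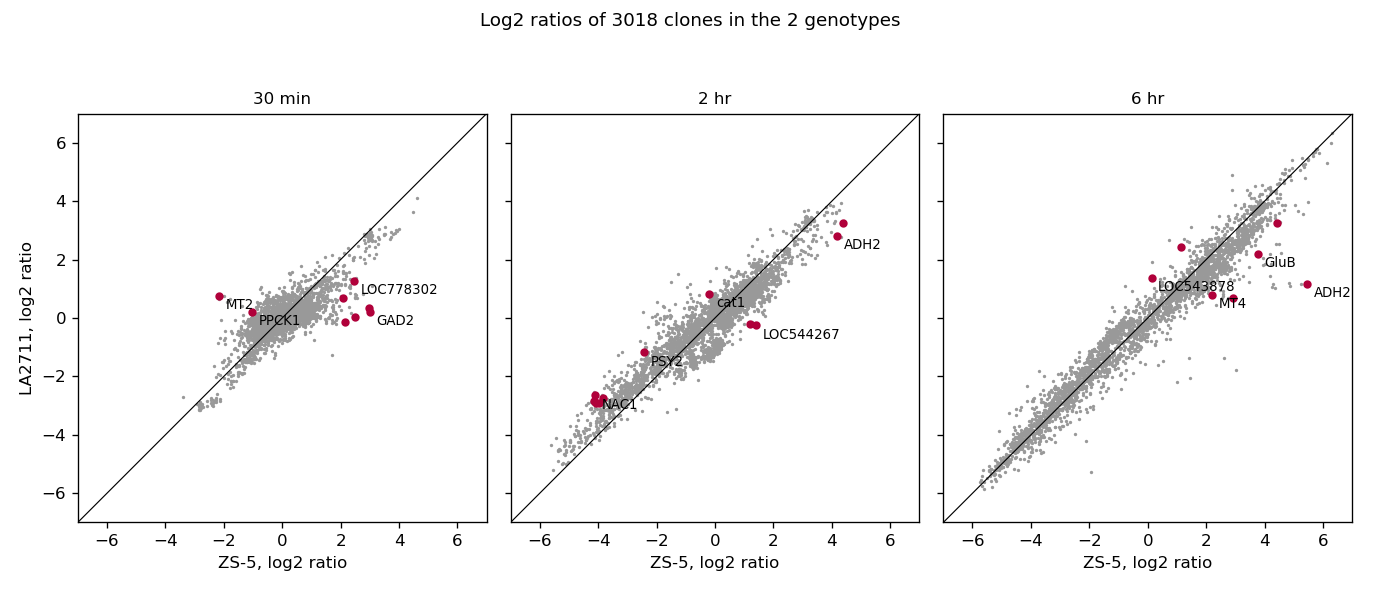
Log2 ratios of 3018 clones in LA2711 (y axis) against ZS-5 (x axis) at each time, each point the mean of 2 centred arrays and the line marking equal values. Red points are named clones whose genotype difference was past 2-fold in both dye orientations, labelled where space allows; of these ADH2 at 6 hr has the largest difference, -4.29.

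Of the gene groups fixed beforehand, as matched by symbol or synonym, most held few named clones on this array. The groups therefore describe single genes. In the jasmonate list, all 7 clones are AOS: over all 6 conditions 1 was called positive and 5 negative, with 7 passing when adjusted over the list alone. Of these 5 negative calls, 4 were lost without centring (adjusted p = 0.061, 0.0634, 0.0681 and 0.0593) and that of AOS (spots 10144 to 10146) was gained (adjusted p = 0.0344). At 6 hr AOS (spots 805 to 807) lay at -3.69, AOS (spots 3373 to 3375) at -3.82, AOS (spots 781 to 783) at -4.58 and AOS (spots 1540 to 1542) at 3.49. In the transcription factor list, all 9 measured clones are NAC1: at 30 min 7 were called positive and 0 negative, and at 6 hr 1 positive (not without centring, adjusted p = 0.164) and 8 negative, with 9 passing when adjusted over the list alone at each of these times. Over all 6 conditions NAC1 (spots 4315 to 4317) lay at -2.42, NAC1 (spots 469 to 471) at -2.30 and NAC1 (spots 3658 to 3660) at -2.44 without passing. In the polyamine and S-adenosylmethionine list, all 5 clones are SAM3: 4 were called positive at 6 hr, among them SAM3 (spots 3181 to 3183) at 2.77, SAM3 (spots 4396 to 4398) at 3.13 and SAM3 (spots 286 to 288) at 1.62, with 4 passing when adjusted over the list alone. With camera's preset correlation 10 of the list results were called, for example NAC1 at 6 hr (adjusted p = 0.0119), AOS at 6 hr (adjusted p = 0.0314) and SAM3 at 6 hr (adjusted p = 0.0314). With an estimated correlation 0 were called, with camera adjusted p = 0.386 for each of these, and with fry 12 were called. The preset treats clones of a single gene as nearly independent, though the estimated correlations at 6 hr were 0.54 for NAC1, 0.93 for SAM3 and 0.07 for AOS. The preset calls are therefore not evidence from several genes.

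The other lists were too small for a list test. Among ethylene genes at 6 hr, ERF3 lay at -2.69 and ACS7, an aminocyclopropane carboxylate synthase, at -2.17, while the JERF1 clones lay at 0.83 and 0.85. Over all 6 conditions 2 of these 4 clones were called positive and 1 negative, and 4 passed when adjusted over the list alone. Both positive calls are those of JERF1 and were lost without centring (adjusted p = 0.0639 and 0.062), and at 6 hr the uncentred JERF1 values were -0.09 and -0.06. Among pathogenesis-related genes, the 3 clones of LOC543878 were called positive, that of spots 6400 to 6402 only with centring (adjusted p = 0.0718 without it, and an uncentred -0.16 at 6 hr). NP24-I, an osmotin-like protein, lay at -1.38 ± 0.32 over all conditions (limma adjusted p = 0.0145) and at -2.09 at 6 hr. Of the matched clones, which leave out GluB, 4 of 4 passed when adjusted over the list alone. The 3 clones of PSBR, taken as a marker of green tissue, were all called negative over all conditions, at -3.45, -1.01 and -0.94. In the list of nutrient uptake and assimilation, GS2 lay at 2.65 and 2.48 in its 2 clones and gts1 at 0.59 (adjusted p = 0.124). LKT1, the one ion transporter matched by symbol, was called positive (1.79) and so was TPX2 (1.56), while cat1 lay at 0.12 (limma adjusted p = 0.833). Hsp90-1, the one clone matched in the chaperone list, was called negative (-1.11, limma adjusted p = 0.0106). MTSHP was not matched by symbol and is outside that list. TIP at 0.96 (adjusted p = 0.121) and LOC543916 at 0.97 (adjusted p = 0.0733) did not pass over all 6 conditions.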

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

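The weighing of explanations below used tests chosen after the results were seen. The difference of the response between 6 hr and 30 min was flagged because a test of the difference itself passed, for 2337 clones in all. Of the named clones, 29 were called negative and 27 positive. The naming rule takes 1 clone per gene and 10 per side, and other clones of a gene can differ (NAC1 up to 2.03). On the negative side it gave NAC1 (-6.80), AOS (-6.53), LOC543942 (-4.56), PSBR (-4.27), ribA (-3.37), MTSHP (-3.11), BMY3 (-3.09), AADC1B (-3.03), PPCK1 (-2.48) and DES (-2.22). On the positive side it gave LOC543878 (3.17), TIP (3.01), cat1 (2.90), ADH2 (2.83), SAM3 (2.24), GS2 (2.00), GluB (1.93), gts1 (1.59), LKT1 (1.57) and LOC778326 (1.52). Groups of 2 arrays are too small to test for an array standing apart.

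Before centring, the median of all clones lay at -0.88 in ZS-5 and -1.03 in LA2711 at 6 hr. One technical explanation is a single offset on every spot of these arrays. The 105 clones within 0.25 of 0 at 30 min and 2 hr in both genotypes argue against it, since their 6 hr medians were 0.07 in ZS-5 (quartiles 0.01 and 0.15) and -0.10 in LA2711 (quartiles -0.16 and -0.03). This is clearest in ZS-5, where the medians of all clones at 30 min and 2 hr were -0.02 and 0.01. In LA2711 they were 0.20 and -0.33, and the 105 clones already lay at 0.39 at 2 hr after centring. Median centring, fixed before the data were examined, places these clones at 0.92 and 0.87 at 6 hr, so the uncentred split of positive and negative calls may describe the 6 hr arrays better. Open remain an offset on spots that bind plant RNA only, if the 105 clones bind none (0 of them are named and intensities were not used here), and a true excess of clones on one side.

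The clones of one gene name did not always behave alike. The difference between 2 clones on the same arrays does not depend on centring, and its SE here is from the spread between genotypes within times. For AOS the largest 6 hr difference was 8.74 ± 0.34 (SE, mean of both genotypes, spread from 6 conditions), with spots 1540 to 1542 positive and spots 1384 to 1386 negative on all 4 arrays. For NAC1 it was 6.87 ± 0.34, but spots 3769 to 3771, the higher clone, reached -0.60 uncentred. NAC1 clones were therefore also compared at 2 hr. The SE allows neither for this choice of time nor for taking the largest difference. There the largest difference, between the clones of spots 4192 to 4194 and 3064 to 3066, was 4.70 ± 0.32. The first lay at 0.87 or more uncentred and the second at -3.07 or less. For MT2 the largest 6 hr difference was 5.11 ± 0.85, with spots 7225 to 7227 at 0.83 or more uncentred and spots 8869 to 8871 at -2.78 or less. Except for the NAC1 pair at 6 hr, these sides held on all 4 arrays with and without centring, which argues against one transcript behind all clones of each name. The positive 6 hr call of MT2 was lost without centring (limma adjusted p = 0.14), but the difference between the clones stayed. The value fell from 2.09 ± 0.54 to 1.17 ± 0.66 (SE, mean of both genotypes, spread from 6 conditions). A wrong name or a related gene may account for these clones, and no value used here separates these. Clones of PSBR shared a side but ranged from -5.17 to -1.27 at 6 hr, and this spread was not tested.

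Which RNA is the numerator could not be told apart. If it is the control, the 3 clones at least 8-fold positive on all 4 arrays at 30 min would need RNA half-lives of 10 min or less. If it is the treated RNA, the 41 clones at least 16-fold negative on all 4 arrays at 2 hr would need half-lives of 30 min or less. Half-lives of these transcripts are not known here, so these values cannot decide and neither reading is excluded. By the pattern of decimals, the deposited values are control over treated if the underlying ratio was Cy5 over Cy3. They are treated over control if it was Cy3 over Cy5.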

How the results depend on the processing

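Keeping spots at the limits, scaling arrays to one median absolute deviation in the tested comparisons, and treat were added after seeing the data. Except where stated, the cause of a change was not tested. Over all conditions 8 of 9 alternatives stayed within 1.5 times the count, at 2 hr 8 of 9 and at 6 hr 8 of 9, but in ZS-5, in LA2711 and at 30 min only 3 of 9 did. With 12 separate arrays, which counts each pair as 2 samples, 2138 clones were called in ZS-5, 1642 in LA2711, 219 between genotypes and 1280 at 30 min. With a dye term these counts were 2072, 1431, 270 and 1368. Quantile normalisation gave 979 in ZS-5, 936 in LA2711, 1665 at 30 min and 1114 for 6 hr minus 30 min. Scaling to one median absolute deviation gave 473, 699 and 1384 for the first 3 of these, 1619 at 6 hr and 808 for 6 hr minus 30 min. Both force arrays of small and large ratios to one spread. Treat against 2-fold gave 167 over all conditions, 45 in ZS-5, 44 in LA2711, 120 at 30 min, 813 at 2 hr and 1437 for 6 hr minus 30 min. Keeping spots at the limits left all 8 counts within 1.5 times.

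Some named clones changed sign. In 6 hr minus 30 min, under quantile normalisation GS2 was at -0.19, LKT1 at -0.41, LOC778326 at -0.61 and AADC1B at 0.01. Under the scaling SAM3 was at -0.35, GS2 at -1.95, GluB at -0.74, LKT1 at -1.14, LOC778326 at -5.20, ribA at 0.02 and AADC1B at 1.35. Without centring, JERF1 at 6 hr was at -0.06 and -0.09 and LOC543878 (spots 6400 to 6402) at -0.16. No clone chosen for the size of its change within a comparison changed sign without centring, and of their 114 values 11 lost the call and 1 gained it. Of the 616 values of all 77 named clones in the 8 comparisons, 54 lost the call, 20 gained it and 27 changed sign, of which 5 were called with centring.

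The repeat numbers do not pair the samples. Half-differences of repeat 1 minus 2 correlated across clones from -0.56 to 0.86 over 15 pairs of conditions, and by dye from 0.45 to 0.86, so the numbers follow the dyes, reversed in ZS-5 at 30 min. With the repeat number as a replicate block on 12 arrays, 2070 clones were called in ZS-5, 1422 in LA2711, 269 between genotypes and 1350 at 30 min, and 2496 over all conditions.

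Without 1 array, counts ranged from 1726 to 1803 over all conditions, 159 to 191 in ZS-5, 124 to 144 in LA2711, 0 to 0 between genotypes, 486 to 668 at 30 min, 2012 to 2094 at 2 hr, 2616 to 2651 at 6 hr and 2283 to 2352 for 6 hr minus 30 min. Without both arrays of a condition they ranged from 605 to 1945, 0 to 975, 0 to 266, 0 to 12, 238 to 622, 1456 to 2092, 2397 to 2647 and 1745 to 2415. Moves over 1.5 times in ZS-5 came without ZS-5 30 min (975), ZS-5 2 hr (0), ZS-5 6 hr (59) and LA2711 2 hr (46). In LA2711 they came without ZS-5 30 min (266), ZS-5 2 hr (45), LA2711 30 min (62), LA2711 2 hr (0) and LA2711 6 hr (0). Between genotypes the count was 12 without either 30 min pair and 1 without either 6 hr pair.

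Clones past 1.5-fold on both arrays numbered 1186 in ZS-5 and 579 in LA2711 at 30 min, and 1861 in LA2711 at 2 hr. Past 3-fold there were 221 and 137 at 30 min, and 888 and 731 at 2 hr. After the scaling 1223 and 929 passed 2-fold at 30 min, and 1276 and 1267 at 6 hr. On 1 array alone ZS-5 had 574 to 742, 1596 to 1609 and 2375 to 2386 at the 3 times, and LA2711 376 to 384, 1389 to 1421 and 2194 to 2215. Camera with an estimated correlation called 0 of the gene list results, against 10 with its preset and 12 with fry. One clone per gene could not be run for the lists, which fall under 5 clones.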

Other observations

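The tests and counts here were chosen after the results were seen. At single times the genotypes differed by size in ways the mean over times does not show. Past 2-fold in both dye orientations, LA2711 minus ZS-5 was positive for 49 and negative for 61 clones at 30 min, 116 and 98 at 2 hr, and 27 and 71 at 6 hr. The response was larger in ZS-5 for 96 of these clones and in LA2711 for 14 at 30 min, for 144 and 70 at 2 hr, and for 72 and 26 at 6 hr. These counts depend on centring: without it the differences were positive for 126 and negative for 37 clones at 30 min, 39 and 306 at 2 hr, and 22 and 119 at 6 hr, with the larger response in ZS-5 for 118, 143 and 102 and in LA2711 for 45, 202 and 39. At 30 min GAD2 lay at 3.0 in ZS-5 and 0.20 in LA2711, LOC543916 at 2.98 and 0.33, LOC543878 (spots 7648 to 7650) at 2.48 and 0.04, and TPX2 at 2.15 and -0.15 (0.07 uncentred). MT2 (spots 7225 to 7227) lay at -2.15 in ZS-5 and 0.77 in LA2711. At 2 hr LOC544267 (spots 5749 to 5751) lay at 1.40 and -0.25, and the 5 NAC1 clones past 2-fold were less negative in LA2711 by 1.06 to 1.46, but only by 0.70 to 1.10 without centring, where none stayed past 2-fold in both dye orientations. At 6 hr ADH2 lay at 5.45 and 1.16 (4.60 and 0.18 uncentred), a difference of -4.61 in one dye orientation and -3.98 in the other, and the metallothionein gene MT4 at 2.21 and 0.80 (1.36 and -0.18 uncentred). Each difference rests on 1 pair of plants or pools, so none of them was tested over replicates.

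Across all clones, the SD of the log2 ratios in LA2711 over that in ZS-5 was 0.80 at 30 min, 0.87 at 2 hr and 0.93 at 6 hr. In arrays of one dye orientation it was 0.80 and 0.85, 0.87 and 0.87, and 0.94 and 0.93. With 3 conditions against 3 there are 10 splits, too few for a share under 0.05. The genotype split gave 0 clones and the highest of the others 9.

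On all 12 arrays 89 clones were past 2-fold on the positive side, among them the 12 clones of LOC778326, and 91 on the negative side, among them AADC1B, 1 clone of AOS and 1 of MT2. Positive at 30 min and negative at 6 hr, past 2-fold on all 8 arrays, were 21 clones, of which 2 are NAC1 and the others unnamed, and 0 clones went the other way. Without centring these counts were 79, 71, 29 and 0, with 11 clones of LOC778326 in the first set, 1 clone of AOS but neither AADC1B nor MT2 in the second, and 3 clones of NAC1 in the third.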
